A study of Mus musculus with 7 samples.

How the data were processed

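RNA was measured in regulatory T cells (Tregs) sorted from spleens of C57BL/6 mice with a red fluorescent reporter of Foxp3, 72 h after an injection of 20 ug of the IL-2/CD25 fusion protein (FP, 4 samples) or of 100 uL of PBS (3 samples). Per the labels, the authors extracted RNA with TRIzol and a column, made libraries from 25 ng of total RNA with a kit that removes ribosomal RNA, and sequenced them on a NextSeq 500. The authors mapped the reads to the mouse genome GRCm38 with STAR (given as 2.5.0 in the design text and as 2.5.0b in the processing notes) and counted them per GENCODE M13 gene with featureCounts 1.5.0. They called genes with DESeq2 at a false discovery rate under 0.05. The strand setting and the treatment of reads that map to several places were not given in the sources used here.

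The deposited values are raw counts per gene, with no normalization, for 51138 genes in 7 columns, and each column was matched to its sample by name. Symbols were found for 50376 gene identifiers and not for 762, which held at most 0.144% of the counts of a library. Coordinates and overlaps with other genes came from a GENCODE annotation of the same genome build that is newer than M13. Of the 184 genes followed singly, 46 overlap another tested gene, 17 of them a gene on the same strand and 38 a gene on the opposite strand, and their counts are less certain because the strand setting is not known.

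Total counts ran from 9956509 to 13429878 per library. A count of 0 in a library allows up to 3 counts, which is 0.223 to 0.301 CPM (counts scaled to the library size) in these libraries. Such floors and the 95% counting intervals of ratios cover counting error alone, since reads without molecular identifiers are not independent molecules.

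The 4 FP and the 3 PBS libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes with low counts were left out with filterByExpr, libraries were scaled with trimmed mean of M values (TMM) factors, and the quasi-likelihood test was run with robust empirical Bayes. Adjusted p values of single genes come from this edgeR test, with the Benjamini-Hochberg adjustment over the 15954 genes tested and a threshold of 0.05. CPM values use TMM-scaled library sizes unless a share of all counts is named, and standard errors of log2 fold changes were taken from the quasi-likelihood F statistic.

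Fixed lists of genes were written before the counts were seen: 19 lists of pathways and cell states, 14 lists of markers of cell types that a splenic sort could hold, and 3 lists defined by the pattern of the symbol. No match was found for 4 of the listed genes (Cd244, Ahsp, Trgc1 and Trgc2). Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists of its kind. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move, on balance, one way. Lists with 1 gene tested were given no camera test. Counts adjusted over the list alone use the p values of the list's own genes.

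Single values per library, such as shares of the counts and summed marker CPM, were compared with a two-sided exact permutation test over all 35 assignments of the 7 libraries. The smallest p this test can give is 0.0286. Adjusted values are over the 31 single values tested.

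The rule for named genes was also fixed beforehand. It took 15 genes in every case (Foxp3, Il2ra, Il2rb, Il2rg, Ikzf2, Ctla4, Tnfrsf18, Klrg1, Icos, Il10, Gzmb, Mki67, Cish, Bcl2 and 1 more). It added the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap, and a symbol that is not a predicted model, pseudogene, receptor segment, histone, small RNA or mitochondrial gene. From each pathway list it took up to 3 members past the threshold with the smallest p, and from each marker list the 2 most abundant members. It took 98 genes, of which 3 are not reported here, and 89 more were followed that were chosen after their values were seen; those of them that the text names are marked as such.

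The tests were tried on simulated counts of 15954 genes with changes put into a small share of them. That share was far below the 39.5% called in the data, so the recovery is not that of the real comparison. The edgeR test recovered 9 of 46 genes changed 1.5-fold, 29 of 49 changed 2-fold, 49 of 49 changed 4-fold and 47 of 48 changed 8-fold, and 6.29% of its 143 calls were false. Camera gave p under 0.05 for 2 of 100 random lists of 25 genes. These genes were unchanged and drawn independently of each other. The trial therefore does not cover lists of correlated genes, such as S phase with an estimated correlation of 0.72.

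Alternatives were the size factors of DESeq2, upper-quartile factors, library size alone, the tests of DESeq2 1.42.0 and limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, a fit without small RNA, histone, ribosomal RNA and mitochondrial genes, a fit without the robust option, the replicate number as a block, and each library left out in turn. Alternatives that use a macrophage score were added after the data were seen. All 35 splits of the 7 libraries into 4 and 3 were tested in the same way. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.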

Results

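RNA was sequenced from Tregs, the T cells that restrain immune responses, after sorting from the spleen on a red fluorescent Foxp3 reporter. The groups were 4 samples from mice given FP, a fusion of interleukin-2 with the alpha chain of its receptor (CD25), and 3 samples from mice given PBS, each taken 72 h after the injection. The total counts of FP replicates 1 to 4 were 11111554, 13283833, 11271496 and 13429878, and those of PBS replicates 1 to 3 were 10570297, 12208512 and 9956509. The labels list the replicates as separate samples without saying that each came from a separate mouse, so the p values measure the spread between these samples.

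FP and PBS were compared to ask which transcripts of splenic Tregs differ 72 h after FP. Among the 19 pathway and cell state lists, those of cell division had the highest medians: 44 of 44 G2 and mitosis genes and 45 of 45 S phase genes were higher after FP, with median log2 fold changes of 4.61 and 1.97. The IL-2 receptor chains Il2ra and Il2rb rose 3.22-fold and 2.45-fold, and Gzmb, a granzyme of cytotoxic granules, rose from 2.94 ± 1.51 CPM (SD, n = 3) to 774 ± 158 CPM (SD, n = 4). Most genes of the interferon response (33 of 35) and of oxidative phosphorylation (47 of 50) were higher. Foxp3, the transcription factor that defines Tregs, measured 540 ± 52.9 CPM after FP (SD, n = 4) and 491 ± 7.24 CPM after PBS (SD, n = 3), and did not pass the test. Markers of monocytes and macrophages moved the other way: 14 of 15 were lower after FP, with a median log2 fold change of -3.66.

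Of 15954 genes tested, 6308 (39.5%) differed between the groups, 3355 higher and 2953 lower after FP. A change of at least 2-fold was found for 1209 of the higher and 1217 of the lower genes. The groups did not overlap in 46.7% of the genes tested, where chance gives 5.71%. The split was 53.2% higher with TMM factors, but 33.2% with upper-quartile factors (2399 higher, 4823 lower) and 28.6% with library size alone (2023 higher, 5046 lower). These scalings moved the median log2 fold change of all genes from -0.05 to -0.25 and -0.31, and changes under them are to be read relative to those shifts. The count of changed genes fell to 4088 without PBS replicate 3. The count of lower genes was 1869 without PBS replicate 2 and 1774 without PBS replicate 3.

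In the Treg core list, 15 genes rose, 3 fell and 8 did not pass, and adjusted over the list alone 15 rose and 4 fell. Il2ra (ENSMUSG00000026770.5, GRCm38 chromosome 2, 11642807 to 11693193, plus strand), the high-affinity IL-2 receptor chain, rose from 602 ± 32.6 CPM (SD, n = 3) to 1938 ± 317 CPM (SD, n = 4), a log2 fold change of 1.69 (SE 0.14, adjusted p = 1.65e-05). Socs2, a feedback inhibitor of cytokine signalling, rose by 2.46 on the log2 scale. Ecm1 rose by 1.20, the glucocorticoid-induced receptor Tnfrsf18 by 1.07, the inhibitory receptor Ctla4 by 0.97 and the Treg transcription factor Ikzf2 by 0.54. With library size alone Ikzf2 no longer passed (0.28, adjusted p = 0.128). Foxp3 (ENSMUSG00000039521.12, chromosome X, 7573644 to 7595245, plus strand) had a log2 fold change of 0.14 (SE 0.10, adjusted p = 0.292), which turned to -0.07 with upper-quartile factors and -0.13 with library size alone. It overlaps Flicr on its own strand and Ppp1r3f, Gm36995 and Ccdc22 on the other. The 3 genes that fell, chosen after their values were seen, were Plagl1 (-1.60), the enkephalin gene Penk (-0.97) and the interleukin subunit gene Ebi3 (-0.57). Ebi3 lost its call without FP replicate 1 (adjusted p = 0.0528), FP replicate 3 (0.0525), PBS replicate 2 (0.0841) or PBS replicate 3 (0.107). Camera placed the list above the other genes (adjusted p = 0.00159), with adjusted p = 0.577 with an estimated correlation. The median of the list was 0.47.

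Of the IL-2 and STAT5 targets, 22 rose, 3 fell and 9 did not pass, and adjusted over the list alone 22 rose and 4 fell. Cish, another feedback inhibitor of the pathway, rose by 1.05 on the log2 scale, and the cell cycle kinase gene Cdk6 rose by 1.62. Il2rb, the signalling chain shared by the IL-2 and IL-15 receptors, rose by 1.29 (SE 0.16, adjusted p = 0.000209), from 602 ± 78.0 CPM (SD, n = 3) to 1475 ± 266 CPM (SD, n = 4). Il2rg, the common gamma chain, rose by 0.55. The 3 genes that fell, chosen after their values were seen, were Rhob (-2.15), a small GTPase gene, the phosphatase gene Dusp6 (-1.13) and the prostaglandin receptor gene Ptger2 (-0.69). The survival gene Bcl2 measured 335 ± 24.5 CPM after FP (SD, n = 4) and 358 ± 12.5 CPM after PBS (SD, n = 3). Its log2 fold change was -0.10 (adjusted p = 0.424), and it passed as lower with upper-quartile factors (-0.29, adjusted p = 0.0438) and library size alone (-0.36, adjusted p = 0.0459). Camera gave adjusted p = 3.84e-06 for the list, and adjusted p = 0.576 with an estimated correlation. The list median was 0.82.

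**Figure D1:**
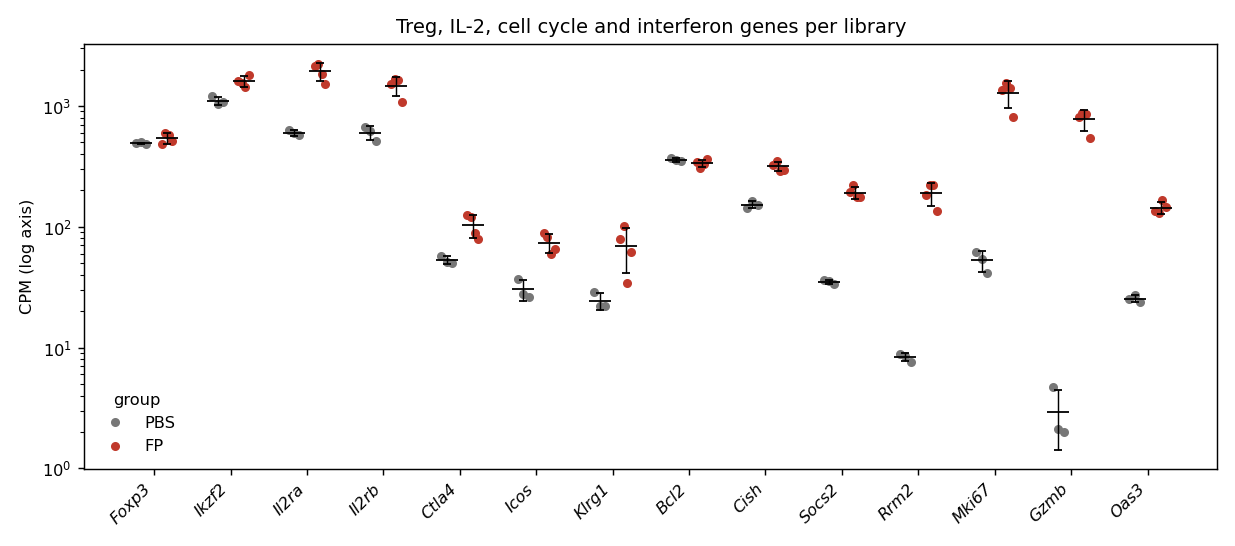
CPM (log axis) of 14 genes in each of the 3 PBS libraries (grey points) and the 4 FP libraries (red points), with the mean and SD as bars; where the SD would reach below the log axis, the lower bar is shortened. Il2ra averaged 602 CPM after PBS and 1938 CPM after FP, and Foxp3 averaged 491 and 540 CPM.

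Of the effector Treg genes, 22 rose, 4 fell and 4 did not pass, with a median log2 fold change of 1.05, and adjusted over the list alone 23 rose and 5 fell. The costimulatory receptor gene Icos rose by 1.28 (SE 0.17) and Klrg1, a receptor of terminally differentiated cells, by 1.51 (SE 0.33). Il10, an inhibitory cytokine, rose by 1.19 (SE 0.33, adjusted p = 0.0169) but did not pass without PBS replicate 3 (0.95, adjusted p = 0.0709). Cd83 fell by 2.59, from 75.4 ± 3.78 CPM (SD, n = 3) to 12.6 ± 3.02 CPM (SD, n = 4). The other genes that fell, chosen after their values were seen, were the checkpoint gene Pdcd1 (-0.54), the adhesion receptor gene Cd44 (-0.53) and Ebi3. The 4 that did not pass, also chosen after their values were seen, were Ccr8 (-0.47), Areg (1.26), Rora (0.31) and Lag3 (0.00). Ccr8 passed as lower without FP replicate 2 (-0.59, adjusted p = 0.0432), with upper-quartile factors (-0.68, adjusted p = 0.00814) and with library size alone (-0.75, adjusted p = 0.00379), and without FP replicate 3 Areg passed as higher (1.57, adjusted p = 0.00885). Camera gave adjusted p = 5.39e-06 for the list, and adjusted p = 0.576 with an estimated correlation. This list shares Gzmb, Nfil3, Fgl2 and Il1rl1 with the IL-2 and STAT5 targets and Il10, Itgae and Ebi3 with Treg core. Treg core and the IL-2 and STAT5 targets share Il2ra, Il2rb, Socs2, Tnfrsf4 and Tnfrsf9, so these lists are not independent.

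Of the resting Treg genes, 10 fell, 3 rose and 11 did not pass, with a median of -0.25, and adjusted over the list alone 10 fell and 4 rose. The cytoskeletal gene Actn1 fell by 0.95 on the log2 scale and Bach2, a repressor that keeps T cells in a resting state, fell by 0.75. Il7r (-1.17), Tcf7 (-0.89) and the lymph node homing receptor gene Ccr7 (-0.80), which also fell, were chosen after their values were seen. The integrin gene Itgb7 rose by 0.98, and so did Ly6c2 (2.42) and Txk (0.49), both chosen after their values were seen; Txk did not pass with library size alone (0.22, adjusted p = 0.154). The list missed the threshold by camera (adjusted p = 0.0514), with adjusted p = 0.577 with an estimated correlation, and passed as lower without FP replicate 2 (0.0380), without PBS replicate 3 (0.0228) and with library size alone (0.0458).

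Among chemokine receptors and homing genes, 12 rose, 3 fell and 12 did not pass (median 0.48), and adjusted over the list alone 13 rose and 6 fell. The median difference from PBS was 0.0107 in FP replicate 4 and 0.519 in the other FP libraries. The mean log2 CPM of the list in FP replicate 4 (6.13) still lay above each PBS library (5.77 to 6.02). Ccr4, a receptor for skin homing, rose by 1.62. The 3 that fell, Ccr3 (-2.52), Ccr6 (-1.52) and Ccr7, were chosen after their values were seen. These genes had adjusted p = 0.0514 by camera and adjusted p = 0.628 with an estimated correlation, and passed as higher without FP replicate 3 (0.0461), without PBS replicate 1 (0.00770) and with library size alone (0.0304). Among costimulatory and coinhibitory receptors 9 rose, 3 fell and 12 did not pass, with the same counts of 9 and 3 adjusted over the list alone. The inhibitory receptor genes Cd200r1 and Tigit rose by 1.27 and 1.26, while Cd200 (-0.72), Cd96 (-0.56) and Pdcd1 fell; Cd200 and Cd96 were chosen after their values were seen. The list median was 0.10, and turned to -0.12 with upper-quartile factors and -0.19 with library size alone. Camera gave adjusted p = 0.145, and adjusted p = 0.715 with an estimated correlation.

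In the cytotoxic list 6 genes rose, 2 fell and 4 did not pass, both over all genes and adjusted over the list alone. Gzmb (ENSMUSG00000015437.4, chromosome 14, 56258838 to 56262260, minus strand) rose by 8.05 on the log2 scale (SE 0.35, adjusted p = 1.57e-06). Gzma, another granzyme gene, had 1266 counts in the FP libraries and 3 in the PBS libraries, a ratio of 337 with a 95% counting interval of 115 to 1638. Nkg7, which acts in granule release, rose by 1.67. Ctsw (-0.78, chosen after its value was seen) and the chemokine gene Ccl5 (-1.0) fell, and Ccl5 did not pass without PBS replicate 1 (-0.81, adjusted p = 0.0530). The 4 that did not pass, chosen after their values were seen, were Gzmm (-0.33), Lamp1 (-0.14), the perforin gene Prf1 (-0.12) and Fasl (0.02, and -0.18 and -0.25 with upper-quartile factors and library size alone). Under the same scalings Lamp1 passed as lower (-0.35 and -0.42, adjusted p = 0.00937 and 0.00667). The list median was 0.41 with a mean of 1.69, and the median turned to -0.08 in DESeq2 and -0.03 with no filter, where more of the listed genes were tested. Cytotoxic genes had adjusted p = 0.0660 by camera, and adjusted p = 0.577 with an estimated correlation.

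Every S phase and G2 and mitosis gene tested was higher after FP, over all genes and adjusted over the list alone. Rrm2, which makes deoxynucleotides, rose by 4.51 on the log2 scale (SE 0.20), from 8.32 ± 0.628 CPM (SD, n = 3) to 189 ± 40.6 CPM (SD, n = 4). Tyms, of thymidylate synthesis, rose by 2.78 and the replication licensing gene Cdc6 by 4.15. Mki67, the proliferation marker, rose by 4.61 (SE 0.26, adjusted p = 3.06e-06), from 52.6 ± 10.7 CPM (SD, n = 3) to 1286 ± 323 CPM (SD, n = 4). Anln, Kif23 and Spag5, of cytokinesis and the spindle, rose by 4.47, 3.96 and 5.39. Camera gave adjusted p = 5.49e-26 for S phase and adjusted p = 1.53e-34 for G2 and mitosis. With an estimated correlation these were adjusted p = 0.464 and adjusted p = 0.375. By fry they were adjusted p = 0.000581 and adjusted p = 8.82e-05. Among the histone genes that are transcribed in S phase, 50 of 52 rose (median 4.95; 50 rose and 1 fell adjusted over the list alone), while Hist2h2be (-0.46) and Hist3h2a (-0.51), chosen after their values were seen, did not pass. Hist3h2a passed as lower without FP replicate 1 and with library size alone (adjusted p = 0.0308 and 0.0331), and Hist2h2be with upper-quartile factors and library size alone (adjusted p = 0.0229 and 0.0217). These genes are near-identical copies, so that single histone genes are uncertain. Camera gave the histone list adjusted p = 9.65e-25, and adjusted p = 0.363 with an estimated correlation. Histone genes held 1.42 ± 0.853% of the counts after FP (SD, n = 4) and 0.0897 ± 0.0110% after PBS (SD, n = 3; exact permutation p = 0.0571, 0.0984 after adjustment).

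The quiescence list did not move one way: 3 genes rose, 6 fell and 11 did not pass, with the same counts of 3 and 6 adjusted over the list alone. The genes that rose encode inhibitors of cyclin-dependent kinases, namely Cdkn1a (4.60), Cdkn2c (3.74) and Cdkn2d (0.99, chosen after its value was seen). Bmyc fell by 1.13. The list median was -0.04 while its mean was 0.34 and camera pointed up (adjusted p = 0.980, and adjusted p = 0.988 with an estimated correlation). The median turned to 0.00 in DESeq2 and to 0.08 without PBS replicate 1, and 5 and 4 members passed without PBS replicate 2 and PBS replicate 3.

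**Figure D2:**
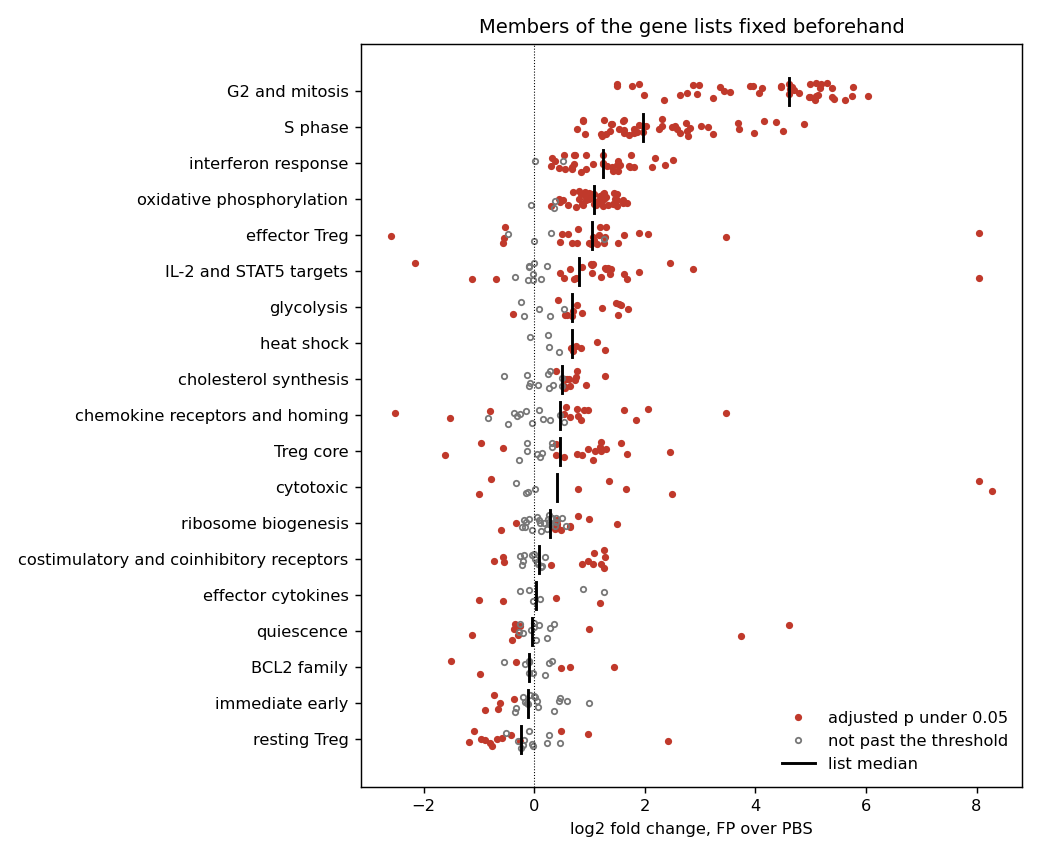
Log2 fold change (FP over PBS) of every tested member of the 19 pathway and cell state lists, in edgeR with TMM factors; red points passed an adjusted p of 0.05, open grey points did not, and black ticks mark list medians. The medians run from -0.25 (resting Treg) to 4.61 (G2 and mitosis), and with upper-quartile factors or library size alone those of effector cytokines and of costimulatory and coinhibitory receptors turn negative.

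Energy metabolism genes were mostly higher. In glycolysis 13 rose, 1 fell and 5 did not pass (median 0.69), and adjusted over the list alone 14 rose and 1 fell. Pgk1, Tpi1 and Gapdh rose by 1.69, 1.51 and 1.56 on the log2 scale. Pdk1 (-0.38), a kinase that inhibits pyruvate dehydrogenase, fell and was chosen after its value was seen. It did not pass without PBS replicate 3 (-0.32, adjusted p = 0.0537). Those that did not pass, also chosen after their values were seen, were Hk2 (0.54), Slc2a1 (0.28), Pfkl (0.09), Pfkm (-0.18) and Slc2a3 (-0.24); Pfkl turned to -0.12 and -0.18 with upper-quartile factors and library size alone, where Slc2a3 passed as lower (-0.45 and -0.51, adjusted p = 0.00859 and 0.0122). Hk2 passed as higher without FP replicate 4 (0.68, adjusted p = 0.0170), as did Slc2a1 without PBS replicate 1 (0.41, adjusted p = 0.0399). Glycolysis had adjusted p = 5.22e-05, and adjusted p = 0.576 with an estimated correlation. In oxidative phosphorylation 47 rose and 3 did not pass (median 1.08), and 48 rose adjusted over the list alone. Cox5a (1.24), Cox5b (1.33) and the ATP synthase gene Atp5g3 (0.99) rose, while Ndufs7 (0.37), Ndufb2 (0.35) and Sdha (-0.05), chosen after their values were seen, did not pass. Ndufs7 and Ndufb2 passed as higher without FP replicate 4 (0.47 and 0.46, adjusted p = 0.00855 and 0.0448), and Sdha as lower with upper-quartile factors and library size alone (-0.26 and -0.32, adjusted p = 0.0298 and 0.0252). This list had adjusted p = 4.71e-13, and adjusted p = 0.577 with an estimated correlation. Of the 17 genes encoded in mitochondria (median 0.43) 0 passed in edgeR, over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, 1 passed in DESeq2 and 0 in limma-voom. They had adjusted p = 0.374, and adjusted p = 0.737 with an estimated correlation.

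In cholesterol synthesis 12 genes rose and 11 did not pass (median 0.51), and adjusted over the list alone 16 rose and 1 fell. Mvd rose by 0.95 and Ebp by 1.29. The number past the threshold was 7 without PBS replicate 2 and 7 without PBS replicate 3. This list had adjusted p = 0.000650 by camera, and adjusted p = 0.577 with an estimated correlation. In ribosome biogenesis 11 rose, 2 fell and 22 did not pass (median 0.29), with 11 and 2 adjusted over the list alone. The mean log2 CPM of this list was 6.20, 6.16, 5.83 and 5.69 in FP replicates 1 to 4. It was 5.78, 5.74 and 5.62 in PBS replicates 1 to 3, so FP replicate 4 lay below PBS replicates 1 and 2. Noc4l rose by 0.65 and Rrp1b by 0.37, and Rrp1b did not pass with upper-quartile factors (0.17, adjusted p = 0.118) or library size alone (0.10, adjusted p = 0.429). Nle1 fell by 0.60 and Polr1b by 0.33; Polr1b was chosen after its value was seen and lost its call without each single library except FP replicate 1 (adjusted p from 0.0656 to 0.201). The number of ribosome biogenesis genes past the threshold was 4 without PBS replicate 3, 5 without FP replicate 2 or PBS replicate 2, and 21 without FP replicate 4. The list had adjusted p = 0.0209 by camera, and adjusted p = 0.756 with an estimated correlation. Camera missed the threshold without FP replicate 1 (0.0740), FP replicate 2 (0.0684) or PBS replicate 3 (0.0678). Of the ribosomal protein genes, 20 rose and 68 did not pass (median 0.70), and 1 rose adjusted over the list alone. Their mean log2 CPM was 8.83, 8.68, 8.01 and 7.57 in FP replicates 1 to 4. It was 7.89, 7.60 and 7.45 in PBS replicates 1 to 3. FP replicates 1 and 2 were the highest, and FP replicate 3 also lay above each PBS library. FP replicate 4 lay below 2 of the PBS libraries. The shares of Rn7sk (3.79, 2.73, 1.28 and 1.07% in FP replicates 1 to 4) and Rpph1 (1.02, 0.774, 0.422 and 0.299%) were also higher in FP replicates 1 and 2 than in FP replicates 3 and 4. By camera the ribosomal protein genes had adjusted p = 1.55e-07, and adjusted p = 0.688 with an estimated correlation. Copies and pseudogenes make single ribosomal protein genes uncertain.

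Of the heat shock genes, 6 rose and 4 did not pass (median 0.69), and 7 rose adjusted over the list alone. The median rise over PBS was 0.23 in FP replicate 4 and 0.813 in the other FP libraries. The chaperone genes Hspa8, Hsp90ab1 and Hspd1 rose by 1.13, 0.75 and 0.67. Those that did not pass, chosen after their values were seen, were Dnajb1 (0.46), Hsph1 (0.26), Dnaja1 (0.25) and Bag3 (-0.08), and with library size alone Hsph1 turned to -0.03 and Dnaja1 to -0.04. Dnajb1 passed as higher without FP replicate 4 or PBS replicate 1 (0.59 and 0.58, adjusted p = 0.00480 and 0.0455), and Dnaja1 without FP replicate 4 (0.36, adjusted p = 0.0445). Only 3 members passed without PBS replicate 2, and 3 without PBS replicate 3. Camera gave adjusted p = 0.0152, and adjusted p = 0.577 with an estimated correlation.

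Genes that answer interferon rose in 33 of 35 cases, over all genes and adjusted over the list alone, with a median log2 fold change of 1.24. Oas3, a sensor of double-stranded RNA, rose by 2.51 (SE 0.11, adjusted p = 1.15e-06), from 25.4 ± 1.70 CPM (SD, n = 3) to 144 ± 15.8 CPM (SD, n = 4). The GTPase genes Iigp1 and Gbp7, of defence within cells, rose by 1.55 and 1.24. Ifi44 (0.52) and Ifit2 (0.02), chosen after their values were seen, did not pass, and Ifit2 turned to -0.18 with upper-quartile factors and -0.25 with library size alone. By camera the list had adjusted p = 8.40e-15, and adjusted p = 0.209 with an estimated correlation. With library size alone 22 members of the list passed.

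Of 24 effector cytokine genes 10 had enough counts to be tested, and of these 2 rose and 2 fell, over all genes and adjusted over the list alone. Il10 and Tgfb1 (0.39) rose, and Ccl5 and Ebi3 fell. Tgfb1 did not pass without PBS replicate 3 (0.36, adjusted p = 0.0871), with upper-quartile factors (0.18, adjusted p = 0.121) or with library size alone (0.11, adjusted p = 0.395). The median of 0.04 turned to -0.02 without FP replicate 1, -0.00 in limma-voom, -0.17 with upper-quartile factors and -0.25 with library size alone. Without PBS replicate 3, 1 member passed. Camera pointed up (adjusted p = 0.980, and adjusted p = 0.988 with an estimated correlation) where fry pointed down (adjusted p = 0.654). In the BCL2 family 3 rose, 3 fell and 9 did not pass, with 3 and 3 adjusted over the list alone. The killer genes Bak1 and Bad rose by 1.44 and 0.64, as did Pmaip1 (0.48), while Bbc3 (-0.98), Bmf (-1.51) and Bcl2l11 (-0.33), which also promote cell death, fell. Pmaip1, Bmf and Bcl2l11 were chosen after their values were seen. Pmaip1 did not pass without FP replicate 1, FP replicate 2 or any single PBS library (adjusted p from 0.0509 to 0.108), nor with upper-quartile factors (0.144) or library size alone (0.285). Bmf did not pass without FP replicate 3 or any single PBS library (0.0556 to 0.0937), nor Bcl2l11 without FP replicates 1, 2 or 4 or PBS replicates 1 or 2 (0.0562 to 0.176). Bad did not pass with library size alone (0.37, adjusted p = 0.0907). Without PBS replicate 1 or PBS replicate 2, 3 members of the family passed. The BCL2 family median was -0.09 where camera pointed up (adjusted p = 0.759, and adjusted p = 0.910 with an estimated correlation). Of the immediate early genes 5 fell and 16 did not pass (median -0.11), and 4 fell adjusted over the list alone. Egr3, Egr1 and Dusp2, which rise within minutes of receptor triggering, fell by 0.89, 0.72 and 0.65, as did Egr2 (-0.61) and Btg2 (-0.36), both chosen after their values were seen. Egr2 did not pass without PBS replicate 1 (adjusted p = 0.0564) or PBS replicate 2 (0.0624), and Btg2 lost its call without FP replicate 3, FP replicate 4, PBS replicate 1, PBS replicate 2 or PBS replicate 3 (0.0937, 0.0614, 0.140, 0.0765 and 0.0928). Without PBS replicate 1 or PBS replicate 2, 3 members passed. The median turned to 0.03, 0.06 and 0.19 without FP replicate 3, FP replicate 4 and PBS replicate 1. Immediate early genes had adjusted p = 0.416 by camera, and adjusted p = 0.910 with an estimated correlation.

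Markers of other cell types were measured beside these groups. Of the monocyte and macrophage genes 14 fell and 1 did not pass, over all genes and adjusted over the list alone. Their summed level was 231 ± 76.6 CPM after FP (SD, n = 4) and 1203 ± 436 CPM after PBS (SD, n = 3; exact permutation p = 0.0286, the smallest this test can give, and 0.0805 after adjustment), higher in each PBS library than in any FP library. Vcam1 (ENSMUSG00000027962.14, chromosome 3, 116109949 to 116129688, minus strand), an adhesion molecule of red pulp macrophages, fell from 314 ± 130 CPM (SD, n = 3) to 10.4 ± 8.27 CPM (SD, n = 4). The receptor gene Csf1r (-3.95) and the haem oxygenase gene Hmox1 (-4.28), chosen after their values were seen, fell as well. Ctss did not pass (-0.09), at 167 ± 38.5 CPM after FP (SD, n = 4) and 178 ± 7.32 CPM after PBS (SD, n = 3). It passed as lower with library size alone (-0.39, adjusted p = 0.0198). Most of the summed level after FP, but not after PBS, came from Ctss, so the sum understates the fall of the other markers. Camera gave the list adjusted p = 4.11e-07, and adjusted p = 0.568 with an estimated correlation.

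B cell markers were split: 7 fell, 2 rose and 6 did not pass (median -0.82), and adjusted over the list alone 8 fell and 2 rose. Cd74, the invariant chain of antigen presentation, fell by 1.94, Ighm rose by 0.46 and Cd79b by 0.73 (chosen after its value was seen). Ighm did not pass with library size alone (0.18, adjusted p = 0.188), and Cd79b did not pass without FP replicate 1, FP replicate 2, PBS replicate 1 or PBS replicate 2 (adjusted p = 0.0588, 0.0707, 0.0572 and 0.110), in limma-voom (0.0548), or with upper-quartile factors and library size alone (0.0680 and 0.0925). H2-Aa (-1.74), of antigen presentation and chosen after its value was seen, fell too, but not without FP replicate 4 or PBS replicate 2 (adjusted p = 0.0537 and 0.0583). Ms4a1 (-1.07), chosen after its value was seen, did not pass, although it passed as lower without FP replicate 4 or PBS replicate 1 (adjusted p = 0.0412 and 0.0364), with upper-quartile factors and library size alone (0.0307 and 0.0251) and with no filter (0.0378). The B cell list had adjusted p = 0.150, and adjusted p = 0.568 with an estimated correlation. The summed B cell markers were 571 ± 61.6 CPM after FP (SD, n = 4) and 596 ± 60.3 CPM after PBS (SD, n = 3; exact permutation p = 0.6, 0.689 after adjustment), mostly from Ighm.

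Of the markers shared by T cells, 3 of 8 rose (median 0.31), over all genes and adjusted over the list alone: Trac (0.53), Cd3d (0.48) and Cd247 (0.44), chosen after their values were seen. Cd247 did not pass without FP replicate 1 (adjusted p = 0.0569), nor Cd3d and Cd247 without FP replicate 2 (0.0592 and 0.0738). None of the 3 passed without PBS replicate 2 (adjusted p = 0.0800, 0.0821 and 0.122) or without PBS replicate 3 (0.0787, 0.109 and 0.117), nor with library size alone (0.102, 0.167 and 0.277), and Cd3d and Cd247 did not pass with upper-quartile factors (0.0839 and 0.130). Cd3e had 0.11, which turned to -0.10 with upper-quartile factors and -0.16 with library size alone, and Trbc2 had 0.47 (adjusted p = 0.0970), passing as higher without FP replicate 3 or FP replicate 4 (adjusted p = 0.0466 and 0.0262). Cd3g (0.19), Cd4 (0.12) and Lck (0.08), chosen after their values were seen, did not pass and turned negative under the same scalings. T cell markers had adjusted p = 0.183 by camera, and adjusted p = 0.582 with an estimated correlation. The conventional T cell markers Bcl6 (-1.37), Cd40lg (-0.98) and Pde3b (-0.80) fell, of 5 tested, over all genes and adjusted over the list alone. Dapl1 (-0.50) and Igfbp4 (0.27, and -0.01 with library size alone) did not pass, although Igfbp4 passed as higher without FP replicate 4 (0.44, adjusted p = 0.0142) and Dapl1 as lower with library size alone (-0.78, adjusted p = 0.0343). Cd40lg, Pde3b and Dapl1 were chosen after their values were seen. This list had a median of -0.80 and adjusted p = 0.150 by camera, and adjusted p = 0.568 with an estimated correlation. By fry it passed as lower (adjusted p = 0.00140). The CD8 T cell markers Cd8b1 (0.30) and Cd8a (-0.12) did not pass in edgeR, DESeq2 or limma-voom, and 0 of them had an unadjusted p under 0.05 in edgeR (list median 0.09; adjusted p = 0.833, and adjusted p = 0.883 with an estimated correlation).

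The constant genes of the T cell receptor gamma chain, Tcrg-C1 and Tcrg-C2, rose by 3.51 and 2.82, whereas Trdc, the constant gene of the delta chain, fell by 0.72 (chosen after its value was seen). Trdc did not pass without FP replicate 1, FP replicate 2, PBS replicate 1 or PBS replicate 2 (adjusted p = 0.101, 0.0712, 0.0970 and 0.213). The 3 genes tested gave the gamma delta list adjusted p = 0.247 by camera, and adjusted p = 0.568 with an estimated correlation, with 2 higher and 1 lower adjusted over the list alone. Among dendritic cell markers Bst2, which is also in the interferon list, rose by 1.32, and Clec9a (-4.31, from 7 counts after FP and 119 after PBS, a ratio of 0.0470 with a 95% counting interval of 0.0185 to 0.0999), Itgax (-2.24) and Zbtb46 (-0.82), chosen after their values were seen, fell. Ccr9 did not pass (-0.31), although it did as lower with upper-quartile factors and library size alone (-0.51 and -0.58, adjusted p = 0.0177 and 0.0117). The summed dendritic markers were 70.03 ± 4.69 CPM after FP (SD, n = 4) and 67.0 ± 3.14 CPM after PBS (SD, n = 3; exact permutation p = 0.400, 0.539 after adjustment). Bst2, which rose, and Ccr9 were the most abundant of these markers, so the sum does not speak for the 3 that fell. The dendritic list had a median of -0.82 and adjusted p = 0.247 by camera, and adjusted p = 0.568 with an estimated correlation. Of 7 erythroid markers 1 fell, the receptor gene Epor (-3.21, chosen after its value was seen), and the haemoglobin gene Hbb-bs did not pass (-0.59), nor did Alas2 (-0.39). The erythroid list median was -0.53, with adjusted p = 0.247 by camera and adjusted p = 0.568 with an estimated correlation. The summed erythroid level was 17.9 ± 8.46 CPM after FP (SD, n = 4) and 27.3 ± 10.6 CPM after PBS (SD, n = 3; exact permutation p = 0.229, 0.338 after adjustment).

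Few markers of the remaining cell types reached the filter. Among plasma cell markers Xbp1 rose by 1.12 and Derl3 did not pass (-0.06), with adjusted p = 0.373 by camera and adjusted p = 0.568 with an estimated correlation. Eomes, a transcription factor of NK cells, fell by 2.12. The neutrophil gene Ltf had 61 counts after FP and 3 after PBS, a ratio of 16.3 with a 95% counting interval of 5.31 to 81.0. The mast cell gene Cpa3 did not pass (-1.59, adjusted p = 0.0559), although it passed as lower without FP replicate 4 (-1.97, adjusted p = 0.0328), with upper-quartile factors and library size alone (adjusted p = 0.0340 and 0.0267) and with no filter (0.0326). Of the platelet genes Itgb3 rose by 0.74 and Itga2b fell by 0.73, and Itga2b lost its call without each single library except FP replicate 1 (adjusted p from 0.0563 to 0.156). Platelet genes had adjusted p = 0.882, and adjusted p = 0.887 with an estimated correlation. Of the stromal genes Col1a1 rose by 1.84, while Pecam1 (-0.14) and Col1a2 (0.65, chosen after its value was seen) did not pass. Pecam1 passed as lower with upper-quartile factors and library size alone (-0.34 and -0.41, adjusted p = 0.00894 and 0.0150). The stromal list had adjusted p = 0.460 by camera and adjusted p = 0.568 with an estimated correlation.

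**Figure D3:**
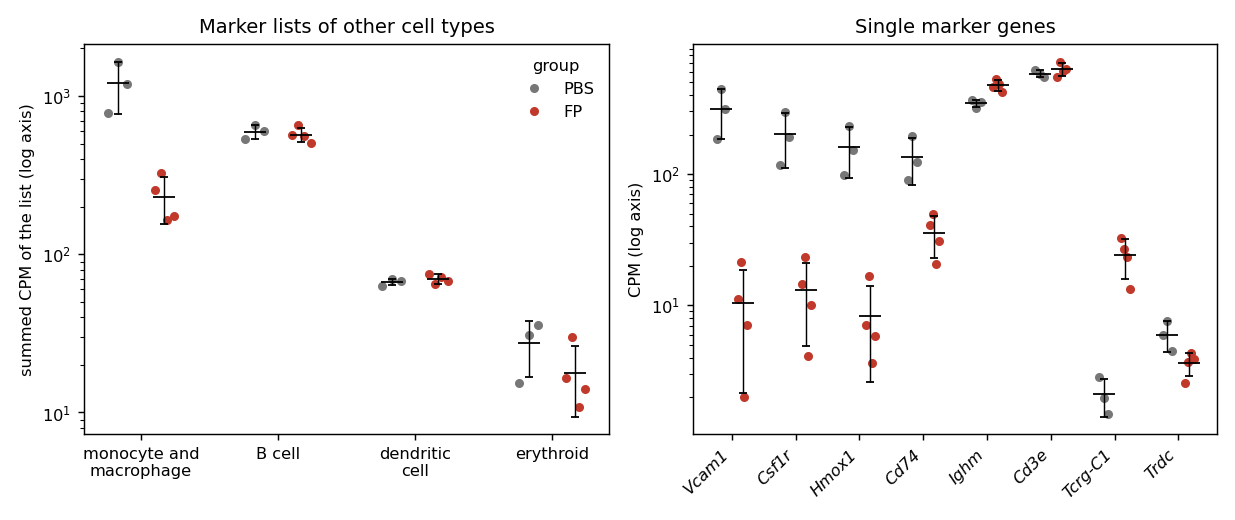
Left, summed CPM (log axis) of 4 marker lists, and right, CPM (log axis) of 8 single genes, in each PBS library (grey points) and each FP library (red points) with the mean and SD as bars. The macrophage sum averaged 1203 CPM after PBS and 231 CPM after FP, most of the latter from Ctss. The B cell sum averaged 596 and 571 CPM. Cd3e (log2 fold change 0.11) turns to -0.10 with upper-quartile factors and -0.16 with library size alone.

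The rule for large changes named 6 rises and 6 falls. Besides Gzma and Gzmb, the rises were Ifitm1 (7.13), an interferon-induced membrane protein gene, and the division genes Cdc25c (6.05), Ska1 (5.89) and Shcbp1 (5.79). Ifitm1 had 756 counts after FP and 4 after PBS, a ratio of 151 with a 95% counting interval of 58.8 to 556. For Cdc25c and Ska1, with 6 and 7 counts after PBS, the ratios were 68.1 (31.1 to 186) and 61.6 (29.7 to 154). The falls were Slco2b1 (-5.99), Paqr9 (-5.51), the integrin gene Itgad (-5.44), the scavenger receptor gene Cd163 (-5.36), Mertk (-5.25), which acts in the uptake of dying cells, and the iron exporter gene Slc40a1 (-5.17). Slc40a1 went from 300 ± 132 CPM after PBS (SD, n = 3) to 8.30 ± 6.10 CPM after FP (SD, n = 4). Across the PBS libraries, these lower genes were highest in PBS replicate 2 and lowest in PBS replicate 1, as was the sum of the macrophage markers (1648 and 776 CPM).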

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

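The search for single libraries far from their group followed a rule fixed before the data were examined, while the tests of explanations and the reading of the splits of the samples were chosen only after the results were seen. In the FP group 215 values (genes, some of them chosen after their values were seen, list means and shares) were searched for a library lying far from the other 3, measured as its gap to the nearest library divided by the whole range of the 4. The search found 14, where chance gives about 1 in 20, or 10.8. PBS, with 3 libraries, was not searched. The first number given for each value is this ratio.

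FP replicate 4 lay far from the others in 7 values: Gzma (0.916; 11.6 CPM against 34.3 to 36.4), Cdkn2c (0.832; 45.7 against 72.0 to 77.3), Rrp1b (0.858; 71.0 against 78.0 to 79.2), Igfbp4 (0.868; 68.9 against 119 to 127), Col1a1 (0.915; 2.64 against 1.28 to 1.40), and the mean log2 CPM of S phase (0.860; 5.44 against 6.03 to 6.13) and of G2 and mitosis (0.856; 5.52 against 6.20 to 6.31). FP replicate 3 was lowest for Cd83 (0.857; 8.06 CPM against 13.6 to 14.5) and the BCL2 family mean (0.923; 4.09 against 4.35 to 4.37). FP replicate 2 was highest for Ltf (0.963; 2.66 CPM against 0.860 to 0.927) and had no Clec9a count (0.852; the others had 0.183 to 0.215 CPM, each below the 3 counts that a 0 allows, so this gap is within counting error). FP replicate 1 was highest for Itga2b (0.836; 3.55 CPM against 2.29 to 2.50) and Plagl1 (0.834; 5.27 against 3.42 to 3.73) and lowest for Pfkm (0.885; 9.67 against 13.7 to 14.3).

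Of the 35 splits into 4 and 3 libraries, only the real one gave as many changed (6308), higher (3355) or lower (2953) genes. The highest counts of the other splits were 3879, 1533 and 2346. A share of 1 in 35 is the smallest these splits can give, so chance is made less likely but is not excluded. The split with 3879 genes set FP replicate 4 together with the 3 PBS libraries, which points to a structure of the samples, and 33 of the 34 other splits gave 0 genes by edgeR. FP replicate 4 does not stand apart alone: on the second principal component (10.7% of the variance) FP replicates 1 and 2 lay at 23.3 and 31.2 and FP replicates 3 and 4 at -32.0 and -32.1. The correlations of log2 CPM were 0.986 between FP replicates 1 and 2 and 0.987 between 3 and 4, against 0.974 to 0.978 across these pairs. What divides the FP libraries in this way, a batch included, was not tested.

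The genes lower by 8-fold or more after FP deviated within the groups together with a score of macrophage markers: over 222 genes, markers left out, the median correlation was 0.794 (quartiles 0.573 and 0.929), so RNA of splenic macrophages in the PBS libraries is a candidate source for them. For the 2531 genes lower by under 4-fold the median was -0.051 (quartiles -0.349 and 0.293). This argues against that source as the main one for most of them. Of these genes 5.49% had a correlation over 0.7, against 5.38% of those that did not pass. The part of macrophage RNA in the 2531 genes cannot be judged from the median correlation. A lower share of Tregs with every other cell type raised alike was tested with the B cell markers. Their median log2 fold change lay 2.84 above that of the macrophage markers (combined SD 0.84). This cannot exclude it, since 2 B cell markers rose after FP and the list need not measure B cells alone. The macrophage list has 16 genes, 15 tested and none in another fixed list. Its most abundant genes were Vcam1 (314 CPM after PBS, 10.4 after FP), Csf1r (201 and 13.1) and Ctss (178 and 167). Ctss was thus not carried by macrophages alone. The 186 genes lower by 4-fold to under 8-fold (median 0.483) stay open, as does that lower share of Tregs. Also open is an effect of FP on splenic macrophages themselves. It cannot be told apart from a difference in sorting because the score parts the groups completely (gap of 1.92 on the log2 scale). The sort on the Foxp3 reporter would remove intact macrophages that lack it, but no value here gives the purity reached.

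The T cell receptor gamma constant genes rose while Trdc, the delta constant gene, fell. The log2 fold change of Trdc was -0.719 (SE 0.25), which argues against gamma delta T cells in the FP libraries. The sum over the gamma constant genes rose 7.7-fold, from 5.37 ± 1.32 to 41.4 ± 13.6 CPM (SD, n = 3 and 4; exact permutation p = 0.0571, all FP libraries above all PBS libraries), which argues against reads moved between near-identical copies. Tcrg-C3 had 69 counts after FP and 0 after PBS. Transcription of the gamma locus in the sorted cells may be the source, a hypothesis found and tested on the same libraries; other technical explanations were not tested.

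FP replicate 4 lay nearer to PBS than the other FP libraries, at -30.3 on the first principal component (75.6% of the variance) against -62.8 to -57.3, with S phase at 1.36 above PBS against 2.11 and oxidative phosphorylation at 0.485 against 1.21 (medians, log2). It lay further from PBS than the others for resting Treg (-0.399 against -0.219), immediate early (-0.622 against 0.0599) and quiescence (-0.125 against -0.0887) and nearly level for Treg core (0.407 against 0.476), and in the oxidative phosphorylation mean FP replicate 3 (6.08) also lay below FP replicates 1 and 2 (6.56 and 6.56). RNA of PBS Tregs mixed into it would need a share of 40.7% (148 genes) and 638 CPM of macrophage markers, and it had 174 CPM, 27.3% of that level (37.5% of the level needed with the lowest PBS library). That argues only against RNA at the macrophage level of the PBS libraries. Treg RNA with less of it would not be seen and stays open. A lower depth of FP replicate 4 is excluded, its total count having rank 1, the highest, of the 4. A weaker response, a lower dose received, a batch shared with FP replicate 3 and a difference in handling stay open and were not tested.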

How the results depend on the processing

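The lists, the rule for named genes, the tests and all alternatives but those with a macrophage score were fixed before the data were examined; the alternatives with a macrophage score were chosen after the data were seen. Of 3121 values of genes followed singly under the alternatives fixed beforehand, 2925 kept their direction and their side of the threshold, and of 3475 under all alternatives 3167 did. The number of changed genes lay between 6198 and 7870 under the alternatives fixed beforehand that kept all libraries, and the replicate block gave 7870. Among the genes followed singly, calls were lost with the factors of DESeq2 (Polr1b, Bcl2l11, Btg2), in DESeq2 (these and Itga2b, Trdc), in limma-voom (Cd79b), with no filter (Itga2b, Ebi3, Polr1b, H2-Aa) and under the replicate block (Itga2b, Polr1b, H2-Aa and Ccr2, chosen after its value was seen). Calls were gained in DESeq2 (Areg, Dnajb1), with no filter (Cpa3, Ndufs7, Hk2, Ms4a1), with small RNA, histone and mitochondrial genes left out (Ndufs7) and under the replicate block (Trbc2, Igfbp4, Cpa3, Alas2, Ndufs7, Ndufb2, Areg, Hk2, Slc2a1, Dnajb1, Dnaja1, Hsph1, Ms4a1).

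The values do not settle whether the replicate numbers of the titles pair the samples. The deviations of FP and PBS libraries with the same number had correlations of 0.219, 0.0702 and 0.0966 across genes. All were positive but below the highest other pair (0.394, FP replicate 4 with PBS replicate 3). FP replicate 4 has no partner by number. The labels also hold running sample numbers, which are not shared between the groups. The deviations run with that order in part: PBS replicate 1 had 0.219 and 0.208 with FP replicates 1 and 2 and -0.329 with FP replicate 4, and PBS replicate 3 had -0.167, -0.323 and 0.394 with the same libraries, while PBS replicate 2 had 0.0213 with FP replicate 3. The deviations of a group sum to 0 for each gene, so those of PBS replicates 1 and 3 are not separate signs of an order. Whether neighbouring numbers mark a shared day or batch is not given, and a shared batch stays open, since no fit used these numbers. At this depth a count of 0 in a library allows up to 3 counts, or 0.223 to 0.301 CPM. The test on simulated counts recovered 19.6% of the 1.5-fold and 59.2% of the 2-fold changes. The simulation changed a far smaller share of the genes than the 39.5% called in the data. Its recovery is therefore not the detection limit of the real comparison. Depth, the number of samples and their spread were not varied apart, so their part in this recovery was not tested.

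With upper-quartile factors 4823 genes were lower, and the medians were 0.27 (Treg core), 0.84 (effector Treg), -0.45 (resting Treg) and 0.61 (IL-2 and STAT5 targets). With library size alone 2023 genes were higher and 5046 lower, and the medians were 0.21, 0.78, -0.51 and 0.54 for the same lists and 1.69 for S phase. These factors moved the median of all genes from -0.05 to -0.25 and -0.31. With library size alone the camera adjusted p was 0.0458 for resting Treg, 0.163 for ribosome biogenesis, 0.0304 for chemokine receptors and homing and 0.0208 for cytotoxic, and the quiescence list pointed down (0.832). With a filter of 1 CPM in 3 libraries the quiescence list also pointed down (0.999). The cause was not tested. Under the replicate block 22 ribosome biogenesis genes passed, and the immediate early list pointed up (0.975, median 0.06). FP replicate 4 has no partner by number, so by construction it adds nothing to the group contrast of that fit. Without FP replicate 4 the count was 21 and the median 0.06 too, though camera pointed down there.

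Camera calls ended with an estimated correlation: adjusted p was 0.577 for Treg core, oxidative phosphorylation, cholesterol synthesis and heat shock, 0.576 for effector Treg, IL-2 and STAT5 targets and glycolysis, 0.464 for S phase, 0.375 for G2 and mitosis, 0.756 for ribosome biogenesis and 0.209 for the interferon response. A list of correlated genes has a wider null spread under that test by construction. By fry, the adjusted p was 8.82e-05 for G2 and mitosis and for the interferon response, 0.000581 for S phase and 0.00198 for effector Treg. It was 0.00219 for IL-2 and STAT5 targets, 0.00414 for glycolysis and 0.0152 for Treg core. Oxidative phosphorylation had 0.0178 and cholesterol synthesis 0.0337, and all these lists pointed up. Ribosome biogenesis (0.292), heat shock (0.0573) and effector cytokines (0.654, down) did not pass. Resting Treg (0.0231, down), chemokine receptors and homing (0.0155) and cytotoxic (0.00275) did. Of the marker lists, conventional T cell (0.00140), monocyte and macrophage (0.00681) and dendritic cell (0.0234) passed as lower by fry. Gamma delta T cell (0.0167), plasma cell (0.0207) and stroma and endothelium (0.0296) passed as higher. The B cell, CD8 T cell, shared T cell, erythroid and platelet lists did not pass. Of the pattern lists, only the histones passed (0.00160, higher). Fry asks another question than camera.

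With single libraries left out in turn the ranges were 4088 to 7277 changed genes and 1774 to 3389 lower genes. The lowest counts came without PBS replicate 3 (4088 changed, 1774 lower) and the next without PBS replicate 2 (4332 changed, 1869 lower), and the highest without FP replicate 4. Of the genes called with all libraries, 2285 higher and 1763 lower genes remained without PBS replicate 3. Members past the threshold were 4 to 8 for quiescence, 7 to 15 for cholesterol synthesis, 4 to 21 for ribosome biogenesis, 3 to 5 for the BCL2 family, 1 to 4 for effector cytokines, 3 to 5 for immediate early and 3 to 8 for heat shock. Camera adjusted p ranged from 0.0228 to 0.213 for resting Treg, 0.477 to 0.961 for quiescence, 0.00208 to 0.0740 for ribosome biogenesis, 0.477 to 0.970 for the BCL2 family, 0.00770 to 0.0763 for chemokine receptors and homing and 0.654 to 0.962 for effector cytokines. Beyond the smaller number of samples, the cause was not tested.

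With the macrophage score as covariate 299 genes changed, 294 higher and 5 lower. The score separated the groups completely (correlation with the group 0.937), so that by construction the fit left little of the group difference to test. Members past the threshold were 2 (Treg core), 4 (effector Treg), 1 (resting Treg), 8 (IL-2 and STAT5 targets), 17 (S phase), 2 (quiescence), 1 (glycolysis), 1 (oxidative phosphorylation), 0 (cholesterol synthesis), 0 (ribosome biogenesis), 1 (BCL2 family), 2 (chemokine receptors and homing), 0 (effector cytokines), 1 (costimulatory and coinhibitory receptors), 3 (cytotoxic), 0 (immediate early), 5 (interferon response) and 0 (heat shock). The medians were 0.75 (Treg core), 1.23 (effector Treg), 1.33 (IL-2 and STAT5 targets) and 2.51 (S phase). Among genes past the threshold with or without the covariate, the log2 fold changes that turned were Cd74 (0.53), Hbb-bs (3.81), Csf1r (0.0185), Adgre1 (0.0013, chosen after its value was seen), Cd44 (0.0701), Ccr3 (0.34), Cd96 (0.0287), Btg2 (0.16), Itgax (0.95) and H2-Aa (1.77). Those of Ctss, Sdha, Ifi44, Ifit2, Gzmm, Lamp1, Bag3, Hist3h2a and Ms4a1, which passed in neither fit, turned as well. Without the genes that tracked the score 6216 genes changed, 3320 higher and 2896 lower.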

Other observations

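The lists of this part and the values taken from them were chosen after the values were seen. The camera p values of these lists are therefore no independent evidence. All 17 genes of the 20S proteasome rose after FP (median log2 fold change 1.17), with Psma5 at 1.40, Psmb10 at 0.98 and Psmb8, which the interferon list also holds, at 1.24. By camera the adjusted p was 1.43e-07, and 0.188 with an estimated correlation. Of 19 genes of the S100, annexin and galectin families with Vim, 16 rose, Anxa3 fell by 3.45 (9 counts after FP, a ratio of 0.0877 with a 95% counting interval of 0.0388 to 0.175), and Anxa1 and Lgals8 did not pass (median 1.42; adjusted p = 2.09e-07, and 0.150 with an estimated correlation). S100a6 rose from 21.8 ± 7.69 to 314 ± 70.9 CPM and Vim from 278 ± 44.6 to 1613 ± 364 CPM (SD, n = 3 and 4), and the log2 fold changes of Lgals1 and Anxa2 were 3.79 and 3.58.

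Of 5 Ifitm genes, Ifitm1 (7.13), Ifitm3 (4.58), Ifitm2 (4.44) and Ifitm6 (3.84) rose and Ifitm10 fell by 2.46 on the log2 scale (adjusted p = 0.00238, and 0.150 with an estimated correlation). Ifitm1 and Ifitm6 had 4 and 5 counts after PBS, and their ratios were 151 and 14.9 with 95% counting intervals of 58.8 to 556 and 6.15 to 46.9. The 4 T cell receptor gamma constant genes rose (adjusted p = 0.00109, and 0.150 with an estimated correlation). None of the 4 lists passed with an estimated correlation.

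Malat1 made up 0.638 ± 0.227% of the counts after FP and 1.58 ± 0.290% after PBS (SD, n = 4 and 3; exact permutation p = 0.0286, adjusted 0.0805). The share of Gm26917 was 9.32 ± 0.596% after FP and 8.68 ± 0.657% after PBS (exact permutation p = 0.257). Rank correlations of the log2 fold change with exon length and GC content were -0.03 and 0.03 across genes, which are not independent replicates.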
